A study of Mus musculus with 11 samples.

How the data were processed

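RNA from the ventricular myocardium of 11 mice was sequenced, per the labels' protocols with 25 ± 3 M reads per sample. The deposited table holds raw counts per Ensembl gene, with 1 column per sample, and its values were checked to be whole numbers with totals that differ between samples. Per the submitters' processing notes the authors used STAR 2.5.1, featureCounts and DESeq2 with genome build GRCm38. The role of each tool, the annotation version, the strand setting and the treatment of reads with several alignments were not given in the sources used here. Every column was used (0 columns were left out).

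Of 46517 gene identifiers 46005 matched a symbol in GENCODE M21 and 512 did not, and the unmatched held 0.0198% of counts. There were 22282 genes without a count. Total counts ran from 1.48e+07 to 1.73e+07 per library, and 16615 to 18606 genes had a count. At this depth 3 counts equal 0.143 to 0.278 CPM in a single library. Floors and intervals for genes with 0 to 3 counts in a group (3 counts over the group; 95% intervals) cover counting error only, and not the spread between mice.

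Samples were grouped by the genotype and treatment labels into 4 groups, with the label WT read as Lmnb2 WT. All titles begin with TAC, sham samples included, so surgery was taken from the treatment label. Title numbers ran from 1101 to 1138 in TAC and from 1301 to 1376 in sham samples, so that any batch that follows these numbers is confounded with surgery. The letter M or F that ends each title was F in 3 samples and M in 8, and was used only as a covariate or to select samples. It followed sex as read from the female transcript Xist and the Y chromosome gene Ddx3y. Xist measured 61.9 to 152 CPM in F, and Ddx3y 0.572 CPM or less in F and 51.9 CPM or more in M. In M, Xist measured 0.157 CPM or less in the sham libraries and 2.63 to 7.28 CPM in the TAC libraries. This low signal followed surgery, and its cause was not tested. Both WT sham titles end in M, while KO sham 2, WT TAC 1 and KO TAC 3 have F. Sex is therefore not balanced in TAC against sham in WT, in KO against WT after sham, or in the interaction. Nothing in the labels pairs the samples.

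Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (14619 tested), libraries were scaled by TMM, and 1 mean per group was fitted to all 11 libraries with the quasi-likelihood functions glmQLFit and glmQLFTest (7 residual degrees of freedom). The 5 contrasts were TAC against sham in WT and in KO, KO against WT after sham and after TAC, and the interaction, with TAC against sham over both genotypes as a sixth fit. Tests were 2-sided, and p-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change over the root of the F statistic and are approximate. Group values are means of TMM-scaled CPM with the SD, and log2 CPM used a prior count of 2.

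A set of 32 gene lists, written from general knowledge before the data were examined, was tested with camera in limma 3.58.1 on log2 CPM, with the preset correlation of 0.01, for lists with at least 5 tested members. The same lists were tested with the correlation estimated from the data and with fry. List p-values were adjusted over the lists of a contrast, and gene p-values also over each list alone. The lists cover hypertrophy and fetal, mature cardiomyocyte, ion channel, matrix, fatty acid oxidation, respiratory chain, tricarboxylic acid and branched chain amino acid, glycolysis, cell cycle, nuclear lamina and envelope, nuclear pore, nuclear transport receptor, immediate early, ERK feedback, heat shock and oxidative stress, integrated stress, p53, cytokine, interferon and circadian genes. They also cover markers of fibroblasts, endothelium, pericytes and smooth muscle, macrophages, lymphocytes, neutrophils and mast cells, epicardium, Schwann cells, fat cells, skeletal muscle, atria and red blood cells. Some genes, such as Nppa and Lum, belong to a pair of lists each.

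The rule for named genes was also set before the data were examined. It takes Lmnb2, Lmnb1 and Lmna, then 8 genes of the hypertrophic response in the surgery and interaction comparisons. It then takes up to 6 rises and 6 falls per contrast among called genes with a mean of at least 1 CPM and no overlap between groups, or the 3 smallest p-values where none passed. Predicted, ribosomal protein and mitochondrially encoded genes are not named by this part. Last come the 4 members with the smallest p of each list that passed or held at least 3 called genes. Other genes in the text, such as Adipoq, Cenpf, Ndufs1, Sdha, Ldhb, Clec3b and 2610507I01Rik, were named after their values were seen. Some genes that the rule selects are not reported here.

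The size of the TAC response was compared between genotypes over genes chosen from the fit without genotype, by exact permutation of the genotype labels within surgery (10 arrangements in sham and 20 in TAC, 200 in all). Lamin genes were permuted in the same way. Markers of library make-up were the share of counts from the mitochondrial genome and from ribosomal protein genes.

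Alternatives set before the data were examined were DESeq2 1.42.0, limma-voom, a robust fit, RLE size factors, library totals alone, no filter on low counts, a filter of at least 1 CPM in 3 samples, removal of mitochondrial and haemoglobin genes, thinning to the smallest library, a fit of only the groups compared, the title letter as a covariate, titles ending in M, other thresholds (adjusted p of 0.1; log2 fold change of 1), prior counts of 0.5 and 5, and leaving out each library. Removal of trends on transcript length and GC content, the ribosomal protein share as a covariate, leaving out KO TAC 1 and WT TAC 3 together, limma-voom for named genes, and genotype over both surgeries were chosen after seeing the data.

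The procedure was tested on simulated data with 200 changed genes among 14619 per contrast. A 2-fold change was called for 1% of changed genes in TAC against sham in WT, 0% in KO, 1% in KO against WT after sham, 6% after TAC and 0% in the interaction. A 4-fold change was called for 47%, 66%, 41%, 58% and 6%, and 2, 5, 1, 4 and 1 unchanged genes were called. For the response size, a simulated difference of -0.6 was estimated as -0.46 (exact permutation p = 0.1). Of 200 random lists 1.5% had a list p under 0.05. Simulated genes varied independently of each other, so this share does not test the preset correlation on lists whose genes vary together. Each simulated gene also had the same spread in all groups. In the data, log2 CPM of replicate libraries correlated with r = 0.953 to 0.967 in sham and 0.896 to 0.957 in TAC groups. For KO against WT after sham, 4.64% of unchanged simulated genes had an unadjusted edgeR p under 0.05, against 185 of 14619 genes in the data. The recovery rates rest on these settings and may differ in the data, above all after sham.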

Results

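RNA was sequenced in bulk from the ventricular myocardium of mice in which Lmnb2, the gene of the nuclear lamina protein lamin B2, was floxed and deleted in cardiomyocytes by a Cre recombinase under the Tnnt2 promoter. Controls carried the same Cre and are called WT, as in the labels. Mice aged 10 to 12 weeks had transverse aortic constriction (TAC), which narrows the aorta and raises the pressure load on the heart, or sham surgery. The 11 libraries fell into 4 groups, with 2 WT sham, 3 KO sham, 3 WT TAC and 3 KO TAC libraries. WT sham 2 carried the genotype label WT and the other controls Lmnb2 WT. The interval from surgery to sampling was not given in the sources used here. Total counts were 1.72e+07 and 1.58e+07 in WT sham 1 and 2, and 1.49e+07, 1.73e+07 and 1.60e+07 in KO sham 1 to 3. They were 1.64e+07, 1.63e+07 and 1.62e+07 in WT TAC 1 to 3, and 1.70e+07, 1.51e+07 and 1.48e+07 in KO TAC 1 to 3. The series concerns nuclear pores and the nuclear import of signaling proteins in cardiomyocytes under stress. The comparisons therefore ask what TAC changed in each genotype, and what loss of lamin B2 changed at rest and after TAC.

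The make-up of the libraries differed within groups as well as between them. Transcripts of the mitochondrial genome took 41.1% ± 11.7 (SD, n = 2) of counts in WT sham, 41.2% ± 4.44 (n = 3) in KO sham, 21.5% ± 8.72 (n = 3) in WT TAC and 28.0% ± 7.03 (n = 3) in KO TAC. Messenger RNAs of ribosomal proteins took 0.976% ± 0.539, 1.23% ± 0.385, 3.72% ± 2.56 and 2.22% ± 1.24 in the same order. Among the TAC libraries this share was 6.32%, 3.62% and 1.21% in WT TAC 1 to 3 and 0.789%, 2.92% and 2.94% in KO TAC 1 to 3. WT TAC 3 and KO TAC 1 had the lowest ribosomal protein shares and the highest mitochondrial shares of the TAC libraries, at 30.5% and 35.9%. Markers of fat cells stood out in WT TAC 3, where Adipoq, the gene of the fat cell hormone adiponectin, reached 6.91 CPM (counts scaled to library size), against 1.37 CPM or less in the other 10 libraries.

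**Figure D1:**
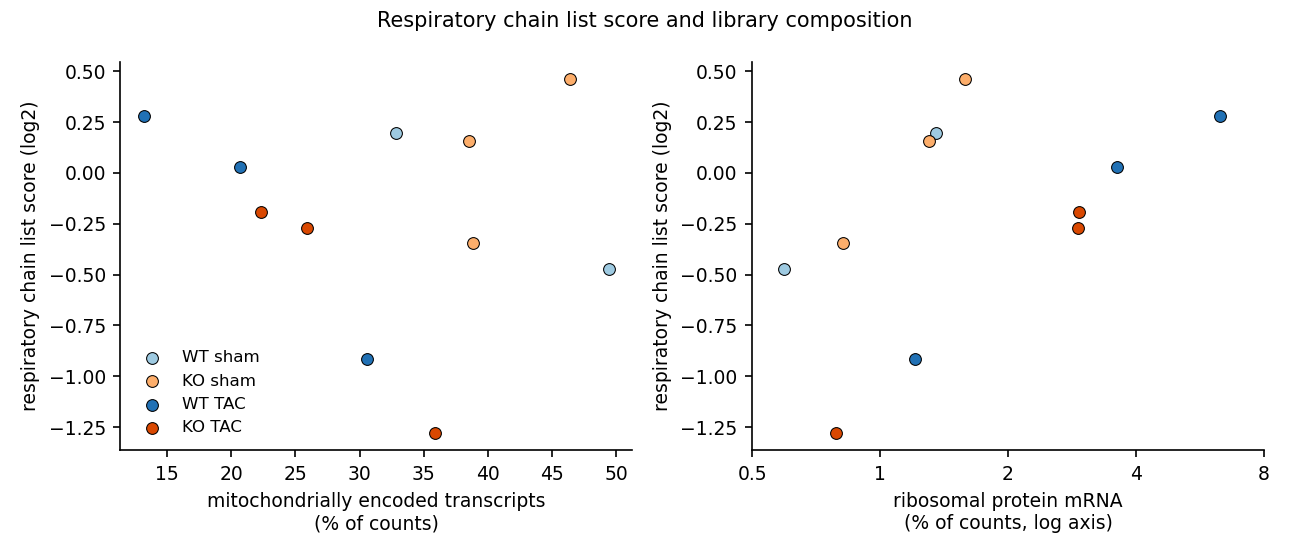
Mean score of 43 respiratory chain and ATP synthase genes (log2, relative to the mean of the 5 sham libraries) against the mitochondrial share and the ribosomal protein share of counts, 1 point per library. Among the 6 TAC libraries the score fell from 0.28 in WT TAC 1, with a ribosomal protein share of 6.32%, to -1.28 in KO TAC 1, with 0.789%.

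Lmnb2 (ENSMUSG00000062075; GRCm38 chromosome 10, 80901203 to 80918245, minus strand), the deleted gene, measured lower in each KO than in each WT library after sham surgery, and not after TAC. It measured 4.44 and 3.86 CPM in WT sham 1 and 2, and 0.649, 1.81 and 2.43 CPM in KO sham 1 to 3. After TAC it measured 2.86, 2.16 and 6.70 CPM in the libraries labelled WT, and 9.72, 3.24 and 4.46 CPM in the libraries labelled KO. The log2 difference between KO and WT was -1.33 ± 0.64 after sham (standard error; edgeR adjusted p = 1) and 0.57 ± 0.55 after TAC (adjusted p = 0.792). Exact permutation of the genotype labels, 2-sided, gave p = 0.2 among the 5 sham libraries (10 arrangements) and p = 0.5 among the 6 TAC libraries (20 arrangements). Neither set has enough arrangements for a 2-sided p under 0.05, even with the labels fully parted. With 1 library left out the difference after TAC ran from -0.07 (without KO TAC 1) to 1.24 (without WT TAC 3). It was 0.39 without WT TAC 1, 0.29 without WT TAC 2 and 0.89 without KO TAC 2, and 0.18 with the ribosomal protein share as a covariate. The count covers the whole gene in bulk tissue, including cells in which this Cre is not active, and the floxed exons were not given in the sources used here. Since Lmnb2 was not lower in the libraries labelled KO after TAC, every direction given below for KO refers to libraries labelled KO.

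Lmnb1 and Lmna, which encode the other nuclear lamins, were measured beside it. Lmnb1 differed between KO and WT by 0.09 ± 0.66 after sham (edgeR adjusted p = 1) and by 1.24 ± 0.56 after TAC (adjusted p = 0.747), with 22.0 CPM in KO TAC 1 and 6.75 CPM or less in the other TAC libraries. Lmna differed by -0.13 ± 0.28 after sham (adjusted p = 1) and by -0.35 ± 0.25 after TAC (adjusted p = 0.752). The gene that parted the genotype labels was Gh (ENSMUSG00000020713; chromosome 11, 106300271 to 106301865, minus strand), which encodes pituitary growth hormone. Its counts were 0 in the 5 libraries labelled WT, and 7, 28 and 29 in KO sham 1 to 3 and 14, 22 and 11 in KO TAC 1 to 3. Counts at Gh were thus at least 14.7-fold higher in KO after sham and at least 14.9-fold higher after TAC, against a floor of 3 counts over the group. Their source was not tested, so expression in the heart is not shown for Gh. Its edgeR adjusted p was 1 after sham and 0.747 after TAC.

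**Figure D2:**
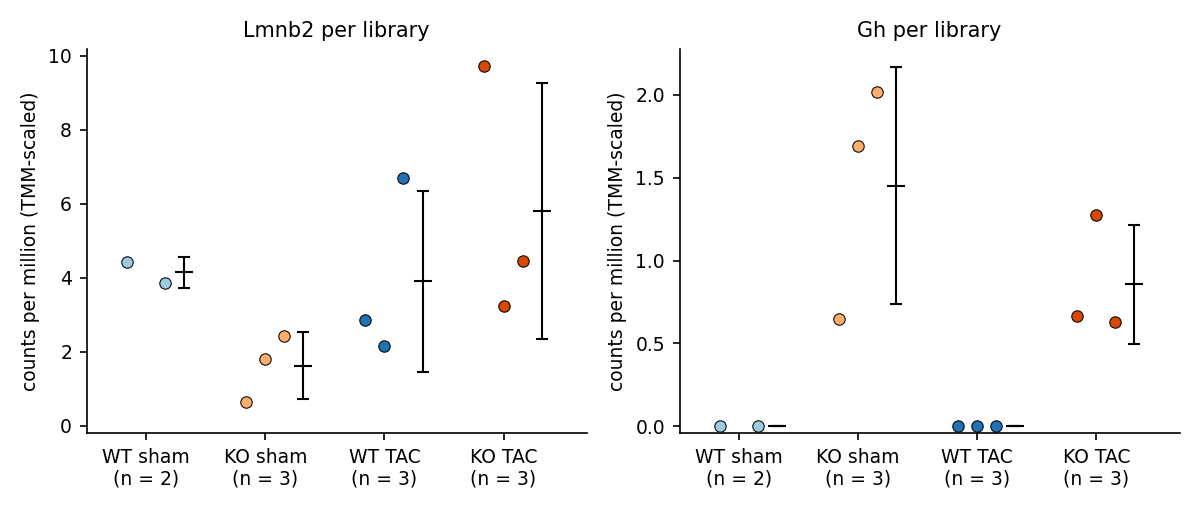
Lmnb2 and Gh in CPM (TMM-scaled), 1 point per library, with the mean and SD of each group beside the points. Lmnb2 lay between 3.86 and 4.44 CPM in WT sham and between 0.649 and 2.43 CPM in KO sham, the groups overlapped after TAC, and Gh had 0 counts in every library labelled WT.

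In the libraries labelled WT, TAC raised genes that the heart expresses before birth and under load (n = 3 TAC and 2 sham libraries; changes are log2 with their standard error). Nppa, the gene of atrial natriuretic peptide, which stretched cardiac muscle secretes, rose by 6.21 ± 1.05 (edgeR adjusted p = 0.00700). Nppb, the gene of brain natriuretic peptide, rose by 4.86 ± 1.004 (adjusted p = 0.0172). Acta1, the skeletal actin of the fetal heart, rose by 2.33 ± 0.58, and Nmrk2, a kinase of NAD synthesis, by 4.44 ± 0.63. Rcan1, a regulator of the phosphatase calcineurin, rose by 1.89 ± 0.32 and Fhl1, a LIM protein of the sarcomere, by 2.16 ± 0.39. Of 25 hypertrophy and fetal genes 12 rose, 0 fell and 13 did not pass, and 17 rose when adjusted over the list alone. Their median change was 1.89 (list adjusted p = 1.2e-08; adjusted p = 0.0975 with an estimated correlation). Myh7, the slow myosin heavy chain of the fetal mouse ventricle, did not pass, at 3.43 ± 1.10 (adjusted p = 0.0782), with 1716 CPM in WT TAC 3 against 111.3 and 101.4 CPM in WT TAC 1 and 2.

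Genes of the mature cardiomyocyte fell in the same comparison. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell (-1.63 ± 0.42; edgeR adjusted p = 0.0368), and Pln, the pump's inhibitor phospholamban (-1.13 ± 0.30). Tcap, which caps titin at the Z-disc, fell (-1.43 ± 0.37) and Cacnb2, a subunit of the calcium channel (-1.20 ± 0.25). Of 25 genes of this list 6 fell and 0 rose, and 8 fell when adjusted over the list alone (median -0.45; adjusted p = 0.144 with an estimated correlation). With library totals in place of TMM scaling 0 fell (median -0.11). The calls of Atp2a2, Pln, Tcap and Cacnb2 were lost in 11, 11, 9 and 4 of 18 other settings, for each without WT sham 1, WT sham 2 or WT TAC 2. Myh6, the adult myosin heavy chain, was at -1.36 ± 0.63 and did not pass (adjusted p = 0.195). Among 25 ion channel and conduction genes 8 fell and 0 rose, and 12 fell and 1 rose when adjusted over the list alone (5 fell and 1 rose with library totals; median -1.14; adjusted p = 0.305 with an estimated correlation). The potassium channel genes Kcnv2, Kcnj3 and Kcnj2 fell (-3.60 ± 0.44, -2.73 ± 0.34 and -2.27 ± 0.34). Kcnip2, whose protein carries the transient outward current with its channel, fell (-2.26 ± 0.43), and Scn4b, a subunit of the sodium channel (-4.78 ± 1.08).

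Matrix genes rose the most as a group. Postn, the gene of periostin made by activated fibroblasts, rose by 6.95 ± 0.58 (edgeR adjusted p = 0.000302), Ltbp2, a protein of elastic fibres, by 6.17 ± 0.65 and Fn1, fibronectin, by 4.28 ± 0.36. The collagen genes Col1a2 and Col1a1 rose by 3.88 ± 0.39 and 3.74 ± 0.63. Of 46 collagen and matrix genes 41 rose, 0 fell and 5 did not pass, and 44 rose when adjusted over the list alone (median 3.50; adjusted p = 0.00473 with an estimated correlation). Of 19 fibroblast markers 4 rose, namely Mfap4 by 5.33 ± 0.54, Mfap5 by 4.15 ± 0.57, Lum by 2.38 ± 0.42 and Pcolce by 1.83 ± 0.27, and 0 fell. Adjusted over the list alone, 7 rose and 2 fell (median 0.84; adjusted p = 0.109 with an estimated correlation). Of 23 macrophage and monocyte markers 5 rose and 0 fell (14 rose by DESeq2, 3 by limma-voom and 13 with library totals), and 15 rose and 1 fell when adjusted over the list alone (median 1.27; adjusted p = 0.228 with an estimated correlation). They included Ctss, a lysosomal protease, by 2.95 ± 0.48, Fcer1g, a receptor subunit, by 2.00 ± 0.40, the complement gene C1qb by 2.02 ± 0.49 and Adgre1, which encodes F4/80, by 1.41 ± 0.37. Of 16 pericyte and smooth muscle markers 2 rose, Cnn1 by 4.05 ± 0.89 and Tagln by 2.80 ± 0.77, and the list did not pass. The 1 that fell was Abcc9, a potassium channel subunit, with a log2 change of -1.94 ± 0.49. Abcc9 is also in the ion channel list and is counted among its falls above. limma-voom called neither rise, and the calls of Tagln, Abcc9 and Cnn1 were lost in 12, 8 and 5 of 18 other settings, that of Abcc9 also with library totals.

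Cell cycle genes also rose in WT. Cdk1, the kinase that drives mitosis, rose by 3.50 ± 0.45 (edgeR adjusted p = 0.00214), Ccna2, cyclin A, by 4.30 ± 0.62 and Anln, a protein of cytokinesis, by 3.98 ± 0.64. Ccnb1, cyclin B, had 0 counts in WT sham and was at least 24.7-fold higher after TAC. Of 40 cell cycle genes 16 rose and 1, Cenpf, fell (21 rose by DESeq2 and 6 by limma-voom), and 22 rose and 1 fell when adjusted over the list alone (median 1.97; adjusted p = 0.166 with an estimated correlation). Among 23 targets of p53 there were 3 that rose, Cdkn1a by 2.65 ± 0.51, Phlda3 by 2.47 ± 0.43 and Trp53inp1 by 1.53 ± 0.39, and 6 rose when adjusted over the list alone (5 with library totals; median 0.55; adjusted p = 0.117 with an estimated correlation). In the stress list Mt2, a metallothionein, and Hmox1, heme oxygenase, rose by 2.89 ± 0.50 and 2.88 ± 0.55. Interferon response genes and epicardial markers passed as lists with 1 gene each that rose, Ifi27l2a of 29 and Aldh1a2 of 7 (medians 0.55 and 2.38; adjusted p = 0.602 and 0.190 with an estimated correlation), both genes named after their values were seen. The interferon list did not pass without WT sham 2 or WT TAC 3, nor the epicardial list with library totals or without WT sham 1, WT TAC 1, WT TAC 3, KO TAC 1 or KO TAC 3. The 5 adipocyte markers also passed as a list, at a median of 2.88, with 0 called by edgeR, DESeq2 or limma-voom and 2 at an unadjusted p under 0.05 (adjusted p = 0.473 with an estimated correlation), but not with a prior count of 0.5, with library totals or without any 1 of the KO TAC libraries. Sod2, the mitochondrial superoxide dismutase, and Hspd1, a mitochondrial chaperone, fell (-1.55 ± 0.30 and -1.60 ± 0.40), calls lost in 4 and 8 of 18 other settings, library totals among them.

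Genes of fuel oxidation fell. Dbt, a subunit of the complex that breaks down branched chain amino acids, fell (-1.94 ± 0.26; edgeR adjusted p = 0.00259) and Ppm1k, the phosphatase that activates this complex (-2.45 ± 0.34). Mccc2 and Ivd of leucine breakdown fell (-1.71 ± 0.25 and -1.71 ± 0.31). Of 33 genes of the tricarboxylic acid cycle and branched chain amino acid breakdown 13 fell and 0 rose, and 27 fell when adjusted over the list alone (median -0.91; adjusted p = 0.00473 with an estimated correlation). Of 37 fatty acid oxidation genes 14 fell and 0 rose, and 21 fell and 1 rose when adjusted over the list alone (median -1.15; adjusted p = 0.0975 with an estimated correlation). Examples were Hadhb and Acaa2 of the mitochondrial beta-oxidation pathway, at -1.60 ± 0.29 and -1.71 ± 0.35, Etfdh, which passes electrons on to ubiquinone, at -1.47 ± 0.29, and Ppara, a transcription factor of lipid use, at -1.33 ± 0.29. With library totals in place of TMM scaling, 2 of the fatty acid genes fell and 1 rose, and 5 of the tricarboxylic acid and amino acid genes fell. Among 26 glycolysis genes 2 rose and 4 fell, with the lactate carrier Slc16a3 up by 2.29 ± 0.48 and Pfkfb1, Slc2a4 and Ldhb among those lower. Of 43 respiratory chain and ATP synthase genes 2 fell, Ndufs1 and Sdha, with a median change of 0.01 that became -1.03 with the ribosomal protein share as a covariate.

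Large rises in WT included genes with 0 to 2 counts in WT sham. Sprr1a, a stress-induced cytoskeletal protein, had 0 counts in WT sham and was at least 812-fold higher after TAC. Wfdc18, Cthrc1, Muc15 and Ifi27l2b were at least 163-fold, 84.4-fold, 65.0-fold and 47.9-fold higher. Libraries differed widely, with Wfdc18 at 41.6 CPM in WT TAC 1 and 0.987 CPM in WT TAC 3. The floor for Wfdc18 was 54.4-fold without WT TAC 1 and 250-fold without WT TAC 3, that for Sprr1a 474-fold without WT TAC 2, and that for Ifi27l2b 31.1-fold without WT TAC 2 and 73.7-fold without WT TAC 3. Serpinb9b, a serine protease inhibitor, had 2 counts in WT sham and a ratio of 1920 (95% counting interval 531 to 15858). This ratio was 1100 without WT TAC 2, 2990 without WT TAC 3 and 1070 without WT sham 2, and at least 567 without WT sham 1, which held both counts. Large falls were those of Scn4b, given above, and of Clcn1, a chloride channel (-4.31 ± 0.65), Acsm5 (-4.27 ± 0.96), Ces1d (-4.12 ± 0.55) and Grhl2 (-3.91 ± 0.95). In the cytokine list Ccl8, a chemokine for monocytes, rose by 4.16 ± 1.01, a call lost in 7 of 18 other settings, limma-voom among them. Ccl11, the eosinophil chemokine, and Il1b, interleukin 1 beta, fell (-3.50 ± 0.72 and -2.54 ± 0.67). Il1b did not pass in 11 of 18 other settings, given below. Among immediate early genes Atf3 rose by 2.61 ± 0.72, and Fos and Dusp1 fell (-2.23 ± 0.58 and -1.40 ± 0.38), calls lost in 9, 8 and 10 of 18 other settings, with library totals for Fos and Dusp1 and with limma-voom for Atf3. In the lists closest to the series' subject edgeR called 0 of 30 nuclear pore genes, 0 of 25 lamina and envelope genes and 0 of 31 transport receptor genes. At an unadjusted p under 0.05 these counts were 2, 5 and 5, DESeq2 called 0, 1 and 0, and limma-voom 0 in each.

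In all, edgeR called 1011 of 14619 genes after TAC in WT, 567 higher and 444 lower. Scaled by library totals alone, which moved the median of all genes to 0.37, the split was 1044 higher and 133 lower, and with limma-voom it was 319 higher and 411 lower. Of 70 calls of named genes in WT 14 did not pass with limma-voom, among them Sprr1a, Wfdc18, Cthrc1, Muc15, Ifi27l2b, Serpinb9b and Il1b. With library totals 12 of the 70 were lost, and 10 were lost in none of the 18 settings run for named genes. The 13 lost in at least 8 settings were Tagln, Atp2a2, Pln, Il1b, Wfdc18, Muc15, Dusp1, Adgre1, Tcap, Atf3, Fos, Hspd1 and Abcc9, each among others without WT sham 1, WT sham 2, WT TAC 1 or WT TAC 2. The count was 30 without WT sham 1, 88 without WT sham 2, 658 without KO sham 3, 398 without WT TAC 1, 363 without WT TAC 2 and 2663 without WT TAC 3. Without both KO TAC 1 and WT TAC 3, which stood apart in composition, it was 4374, a setting chosen after seeing the data.

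In the libraries labelled KO, hypertrophy and fetal genes rose after TAC (n = 3 TAC and 3 sham libraries; changes are log2 with their standard error). Nppa rose by 5.63 ± 0.85 (edgeR adjusted p = 0.00402), Nppb by 3.23 ± 0.78, Acta1 by 4.35 ± 0.54, Nmrk2 by 4.29 ± 0.53 and Rcan1 by 1.81 ± 0.27. Of the 25 hypertrophy and fetal genes 11 rose and 0 fell, and 15 rose when adjusted over the list alone (median 1.66; adjusted p = 0.0593 with an estimated correlation). Myh7 was at 3.57 ± 0.94 and just missed the threshold (adjusted p = 0.0501; 0.0393 with limma-voom), as did Kcnip2 at -1.49 ± 0.39 (adjusted p = 0.0501). Tcap, Cacnb2 and Tnni3, the cardiac troponin I gene, fell (-1.64 ± 0.34, -0.97 ± 0.23 and -1.22 ± 0.31), the 3 genes that fell of the 25 mature cardiomyocyte genes (5 when adjusted over the list alone; median -0.53; adjusted p = 0.0593 with an estimated correlation). With library totals 0 of these genes fell, at a median of -0.0706, and the calls of Cacnb2, Tnni3 and Tcap were lost in 9, 8 and 5 of 18 other settings. Atp2a2 was at -1.33 ± 0.38 (adjusted p = 0.0691), Pln at -0.995 ± 0.27 (adjusted p = 0.0592) and Myh6 at -0.82 ± 0.57 (adjusted p = 0.492). Of the 25 ion channel genes 3 fell, Kcnv2 (-3.88 ± 0.42), Kcnj3 (-2.08 ± 0.31) and Kcnd2 (-1.79 ± 0.34), and 11 when adjusted over the list alone (median -1.08; adjusted p = 0.245 with an estimated correlation).

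Matrix and cell cycle genes were the groups with most members raised in KO. Fn1 rose by 3.78 ± 0.30 (edgeR adjusted p = 0.000176), Postn by 5.58 ± 0.45, Ltbp2 by 5.49 ± 0.53, Col1a2 by 3.23 ± 0.32 and Col1a1 by 3.20 ± 0.52. Of the 46 matrix genes 38 rose and 0 fell, and 44 rose when adjusted over the list alone (median 2.84; adjusted p = 0.00379 with an estimated correlation). Cdk1 rose by 4.29 ± 0.39, Ccna2 by 4.33 ± 0.50, Ccnb2, a cyclin of mitosis, by 5.64 ± 0.63 and Nusap1, a spindle protein, by 4.45 ± 0.51. Of the 40 cell cycle genes 25 rose and 0 fell (26 rose by DESeq2 and 15 by limma-voom), and 29 rose when adjusted over the list alone (median 3.17; adjusted p = 0.0593 with an estimated correlation). Of the 23 macrophage and monocyte markers 6 rose and 0 fell (14 rose by DESeq2, 4 by limma-voom and 15 with library totals), among them Ctss by 2.25 ± 0.40, Adgre1 by 1.86 ± 0.33, Fcer1g by 1.70 ± 0.34 and Ccr2, the receptor of recruited monocytes, by 2.37 ± 0.43 (15 when adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). Of the 19 fibroblast markers 3 rose, Mfap4 by 3.28 ± 0.41, Mfap5 by 3.45 ± 0.47 and Pcolce by 1.40 ± 0.23, and 2 fell, Clec3b and Gsn, the latter (-1.68 ± 0.35) (5 and 2 when adjusted over the list alone; median 0.31; adjusted p = 0.178 with an estimated correlation). With library totals 5 fibroblast markers rose and 0 fell and the list did not pass, nor did it without KO sham 3, KO TAC 1 or KO TAC 3. Of 29 interferon response genes 4 rose (6 by DESeq2, 2 by limma-voom and 12 with library totals), Mx1 by 3.13 ± 0.68, Zbp1 by 2.19 ± 0.51, Irf7 by 1.44 ± 0.37 and Isg15 by 1.53 ± 0.40, and 6 when adjusted over the list alone (median 0.84; adjusted p = 0.210 with an estimated correlation).

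Genes of fuel oxidation fell in KO too. Acaa2, Decr1, Acadm and Eci1 of beta-oxidation fell (-1.89 ± 0.33, -1.31 ± 0.24, -1.28 ± 0.24 and -1.34 ± 0.26; edgeR adjusted p = 0.00705, 0.0106, 0.0116 and 0.0125). Of the 37 fatty acid oxidation genes 13 fell and 0 rose, and 26 fell when adjusted over the list alone (median -0.98; adjusted p = 0.0379 with an estimated correlation). Bckdhb, Dbt, Ppm1k and Mccc2 of branched chain amino acid breakdown fell (-1.30 ± 0.21, -1.28 ± 0.23, -1.67 ± 0.31 and -1.09 ± 0.23). Of the 33 genes of their list 6 fell and 0 rose, and 29 fell when adjusted over the list alone (median -0.79; adjusted p = 0.00379 with an estimated correlation). With library totals in place of TMM scaling, 2 of the fatty acid genes and 1 gene of the other list fell. In glycolysis Slc16a3 and Pfkp, a phosphofructokinase, rose by 3.06 ± 0.44 and 1.65 ± 0.28, and Pfkfb1 and the glucose carrier Slc2a4 fell (-2.38 ± 0.40 and -1.23 ± 0.27). For the 43 respiratory chain genes the median was -0.57, with 0 called by edgeR or limma-voom, 14 lower at an unadjusted p under 0.05 and 10 lower by DESeq2 (list adjusted p = 6.2e-08; adjusted p = 0.477 with an estimated correlation). That median was -0.35 without KO TAC 1, -0.34 without KO sham 1, -0.0709 with library totals and -1.01 with the ribosomal protein share as a covariate. The scores were -1.28, -0.27 and -0.19 in KO TAC 1 to 3, the last 2 within the sham range of -0.47 to 0.46. In the amino acid and unfolded protein stress list Edem1, Pycr1 and Psat1 rose by 1.54 ± 0.29, 2.26 ± 0.54 and 1.75 ± 0.43. Phlda3 was the 1 gene that rose of 23 p53 targets (4 when adjusted over the list alone and 5 with library totals; median 0.43; adjusted p = 0.180 with an estimated correlation), and the list did not pass without KO sham 2 or KO TAC 2.

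Large rises in KO included genes of secreted proteins. Cthrc1, a collagen-associated protein, and Tnfrsf11b, osteoprotegerin, had 0 counts in KO sham and were at least 53.9-fold and 22.0-fold higher after TAC (Cthrc1 27.3-fold without KO TAC 3 and 83.6-fold without KO TAC 1). C1qtnf3 and Serpinb9b, with 2 counts and 1 count in KO sham, had ratios of 470 (95% counting interval 130 to 3887) and 474 (84.8 to 18750). For C1qtnf3 the ratio was 263 without KO TAC 3, 741 without KO TAC 1 and 308 without KO sham 3, and at least 189 without KO sham 2. For Serpinb9b it was 265 without KO TAC 2, 714 without KO TAC 1 and 311 without KO sham 3, and at least 95.3 without KO sham 2. Sprr1a rose by 7.54 ± 1.04. Called genes with large falls included Penk, proenkephalin (-4.04 ± 1.02), Kcnv2, Klhl33 (-3.81 ± 0.91), Inmt (-3.72 ± 0.80), Retnla (-3.66 ± 0.84) and Chrna2, a nicotinic receptor subunit (-3.62 ± 0.93). Of 30 nuclear pore, 25 lamina and envelope and 31 transport receptor genes edgeR again called 0 in each list. At an unadjusted p under 0.05 the counts were 1, 2 and 1, DESeq2 called 0, 1 and 1, and limma-voom 0 in each.

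In all, edgeR called 687 of 14619 genes after TAC in KO, 486 higher and 201 lower. Scaled by library totals alone, which moved the median of all genes to 0.49, the split was 1325 higher and 60 lower, and with limma-voom it was 290 higher and 206 lower. Of 60 calls of named genes in KO 13 did not pass with limma-voom, among them Nppb, Cthrc1, C1qtnf3, Serpinb9b, Tnfrsf11b, Sprr1a, Penk, Inmt, Mx1 and Irf7. With library totals 13 of the 60 were lost, and 25 were lost in none of the 18 settings. The 9 lost in at least 8 settings were Chrna2, Sbk2, Cacnb2, Isg15, Nppb, Penk, Klhl33, Tnni3 and Psat1, each among others without KO sham 3, KO TAC 2 or KO TAC 3. The count was 226, 312 and 255 without KO sham 1, 2 and 3, and 309 and 389 without KO TAC 2 and KO TAC 3. Without both KO TAC 1 and WT TAC 3 it was 2117, and with the ribosomal protein share as a covariate 2324, both chosen after seeing the data.

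**Figure D3:**
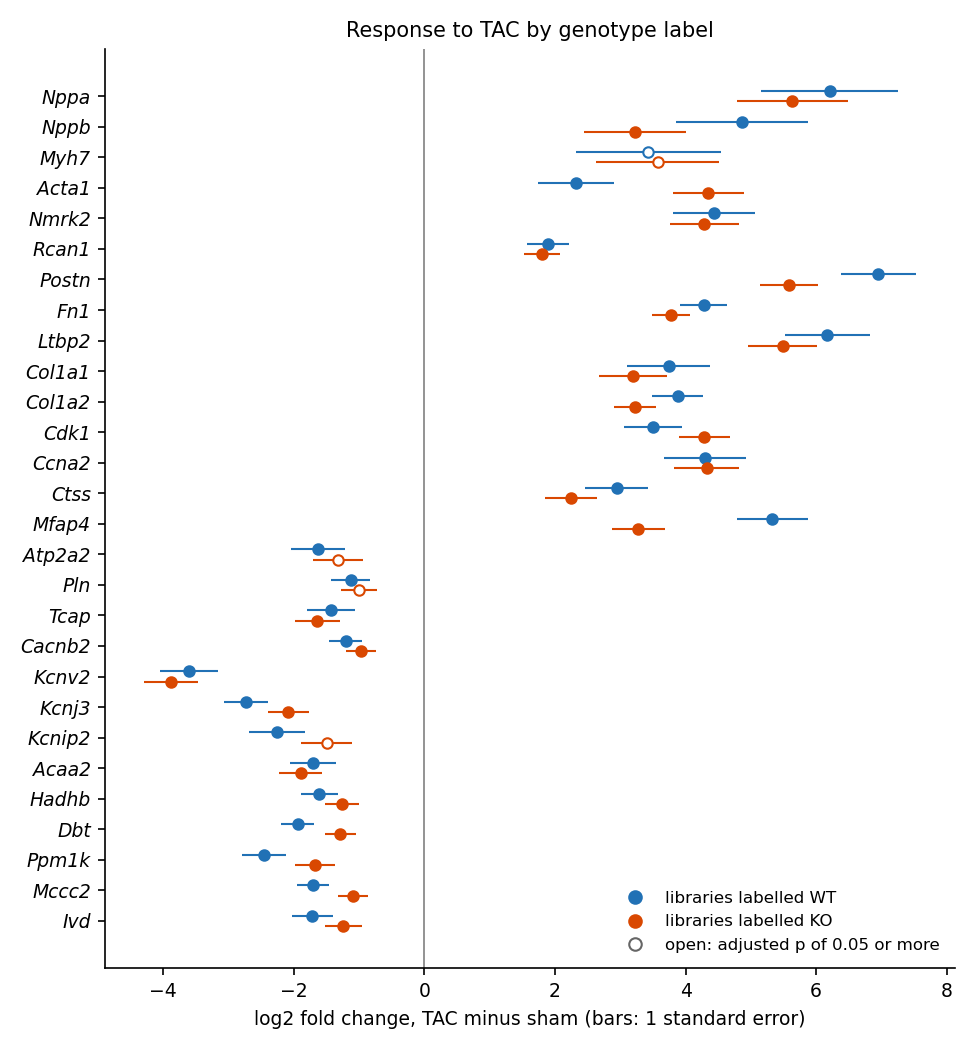
Log2 fold change after TAC of 28 named genes in libraries labelled WT (3 TAC and 2 sham) and KO (3 TAC and 3 sham), with bars of 1 standard error and open points where the edgeR adjusted p was 0.05 or more. Nppa rose by 6.21 in WT and 5.63 in KO, and each gene had the same sign in both.

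Both genotypes shared much of the response. Of the genes called higher, 302 were called in both WT and KO, against 18.8 for independent lists of these sizes, and of those called lower 144, against 6.10. No gene was called in opposite directions (0 of 1252 called in either), and the 2 comparisons share no library. They do share the estimate of the spread and the title numbers that part TAC from sham. The counts for independent lists are therefore a reference only. Among the 1252 genes 99.1% had the same sign, and across all genes, which are not independent replicates, the fold changes correlated with r = 0.67. With genotype left out, edgeR called 3162 genes between 6 TAC and 5 sham libraries, 1717 higher and 1445 lower. Scaled by library totals alone, with the median of all genes at 0.45, this split was 3958 higher and 413 lower, and with limma-voom it was 1330 higher and 1590 lower.

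**Figure D4:**
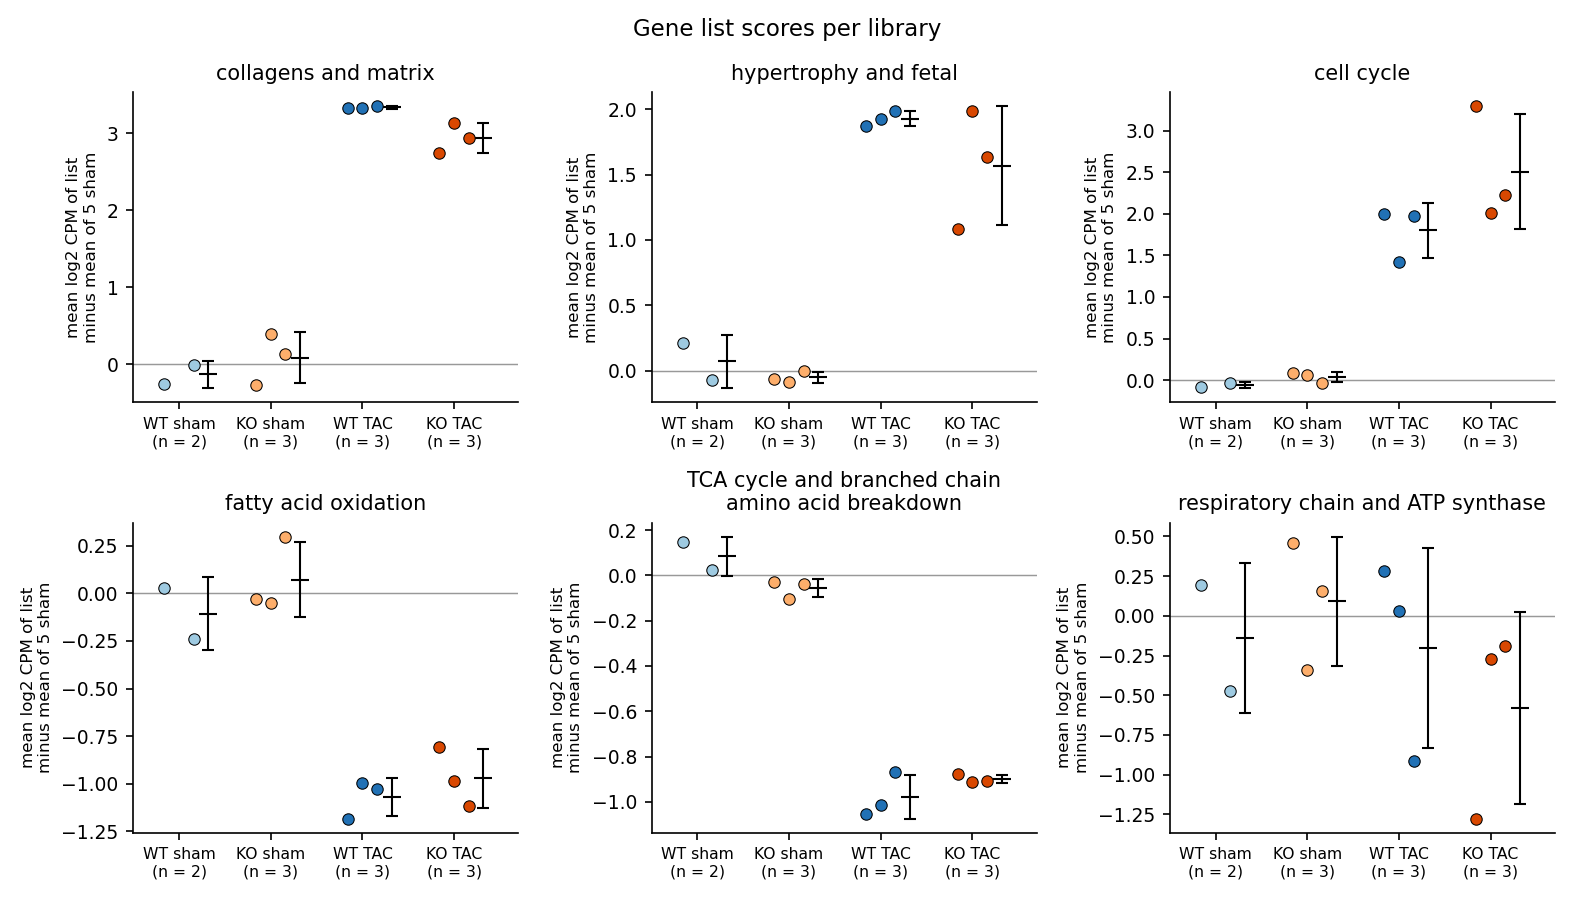
Mean log2 CPM of 6 gene lists per library, relative to the mean of the 5 sham libraries, with the mean and SD of each group beside the points. All 6 TAC libraries lay above the 5 sham libraries for matrix, hypertrophy and cell cycle genes, and below them for fatty acid oxidation and tricarboxylic acid cycle genes, while respiratory chain genes overlapped.

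After sham surgery no gene passed between KO and WT with edgeR, and those with the smallest p are given as values (n = 3 and 2 libraries). Cpxm2, a carboxypeptidase-like secreted protein, measured 59.6 CPM ± 13 (SD) in WT and 9.26 CPM ± 3.57 in KO, a log2 difference of -2.68 ± 0.51 (edgeR adjusted p = 1). Rtn4rl1, a receptor of myelin-associated inhibitors, measured 2.92 CPM ± 1.01 in WT and 10.7 CPM ± 1.96 in KO, a difference of 1.87 ± 0.41 (adjusted p = 1). The third was Gh, described above. edgeR called 0 genes, with 185 at an unadjusted p under 0.05 where 731 are due by chance, limma-voom 0 and DESeq2 3. The 3 were Cpxm2 (adjusted p = 0.00328), Rtn4rl1 (adjusted p = 0.0405) and 2610507I01Rik, an unnamed gene given here after its values were seen, at -4.30 (adjusted p = 1.1e-05). A simulated 4-fold change was recovered for 41% of genes in this comparison and a 2-fold change for 1%.

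Of 32 gene lists 9 passed with the preset correlation after sham, with 0 of their genes called by edgeR, DESeq2 or limma-voom, and 1 fibroblast marker higher when adjusted over the list alone. They were neutrophil and mast cell markers (median -1.38, 5 of 13 lower at an unadjusted p under 0.05), interferon response (0.33), glycolysis (-0.16), collagen and matrix (0.28) and tricarboxylic acid cycle genes (-0.14), with fibroblast (0.24), pericyte (0.27) and endothelial markers (0.25) and heat shock genes (-0.18). With an estimated correlation 0 of the 9 passed (adjusted p = 0.410 to 0.575), and fry called 0 lists. Each of the 9 was lost without at least 1 of the sham libraries, the neutrophil and mast cell list without WT sham 2 and also without KO TAC 3. The matrix, fibroblast and tricarboxylic acid cycle lists did not pass with the title letter, which followed sex, as a covariate. They were also lost without WT sham 1 or without KO sham 2, the only sham library with F. WT sham 2 alone had a neutrophil and mast cell score of 1.55 against -0.25 in the next sham library. Nuclear pore, lamina and envelope, and transport receptor genes had medians of -0.14, 0.01 and -0.14, with 0 genes called by the 3 tools and 0 at an unadjusted p under 0.05.

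After TAC the smallest p among named genes between KO and WT libraries was that of Il1b, the gene of the inflammatory cytokine interleukin 1 beta (n = 3 and 3). It measured 2.81 CPM ± 0.663 (SD) in KO and 0.261 CPM ± 0.0718 in WT, with 43, 54 and 57 counts in KO TAC 1 to 3 and 3, 5 and 6 in WT TAC 1 to 3. The log2 difference was 3.38 ± 0.64 (edgeR adjusted p = 0.747). Car3, a carbonic anhydrase abundant in fat cells, differed in the same direction as the fat cell markers (-7.19 ± 1.53; adjusted p = 0.747), with 35.8 CPM in WT TAC 3, 3.93 and 2.22 CPM in WT TAC 1 and 2, and 0.191 CPM or less in KO TAC. edgeR called 0 genes, with 930 at an unadjusted p under 0.05 where 731 are due by chance, limma-voom 0 and DESeq2 6. The 6 were Il1b (adjusted p = 0.00934), Car3 (0.0224), Gh (0.0279), Adipoq (0.0322) and the unnamed genes 4833412C05Rik and Gm28515 (0.0272 each), the last 3 given here after their values were seen. Without both KO TAC 1 and WT TAC 3 edgeR called 14 genes, a setting chosen after seeing the data, and a simulated 4-fold change was recovered for 58% of genes and a 2-fold change for 6%.

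Of the 32 lists 8 passed with the preset correlation after TAC, and 0 with an estimated correlation or with fry. Cell cycle genes had a median difference of 0.80, with 17 of 40 higher and 0 lower at an unadjusted p under 0.05 and 0 called by the 3 tools (adjusted p = 0.631 with an estimated correlation). KO TAC 1 held the highest cell cycle score, 3.29, against 2.00 and 2.22 in KO TAC 2 and 3 and 2.00, 1.42 and 1.98 in WT TAC 1 to 3. Interferon response genes had a median of 0.57 and endothelial markers of 0.51 (adjusted p = 0.566 and 0.647 with an estimated correlation). Matrix, respiratory chain and hypertrophy genes had medians of -0.37, -0.35 and -0.28 (adjusted p = 0.631, 0.647 and 0.647 with an estimated correlation). Adipocyte markers had a median of -5.86 with the gene at 0 counts set to its bound, and 4 of 5 were lower when adjusted over the list alone. Skeletal muscle markers had a median of -1.11, with 3 of 6 lower when adjusted over the list alone (adjusted p = 0.327 with an estimated correlation for both). The matrix list did not pass without WT TAC 3, the endothelial list without WT TAC 2 or KO TAC 1, and the hypertrophy list without WT TAC 3, KO TAC 1 or KO TAC 3. The respiratory chain list did not pass without WT TAC 1, WT TAC 2 or KO TAC 1, nor the skeletal muscle list without WT TAC 3 or KO TAC 1. Nuclear pore, lamina and envelope, and transport receptor genes had medians of 0.02, 0.10 and -0.04, with 1 gene of each at an unadjusted p under 0.05 and 0 called by the 3 tools.

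The interaction asks whether TAC moved a gene differently in KO than in WT (n = 3, 3, 3 and 2 libraries). Il1b had the smallest p of the named genes, at -2.54 ± 0.67 after TAC in WT (adjusted p = 0.0426) and 2.17 ± 0.60 in KO (adjusted p = 0.0586), with a difference of responses of 4.71 ± 0.90 (edgeR adjusted p = 0.992). It measured 2.38 and 0.709 CPM in WT sham 1 and 2, and its change in WT was -1.41 without WT sham 1 (adjusted p = 0.384) and -3.16 without WT sham 2, and passed in neither. The call in WT was also lost with limma-voom, with library totals, with the title letter as a covariate, and without KO sham 1, KO sham 2, KO sham 3, WT TAC 1, WT TAC 2 or KO TAC 2. Mylpf, a light chain of fast skeletal muscle, had a difference of -5.73 ± 1.23. It rests on 1 count in each WT sham library, with 62, 14 and 15 counts in WT TAC 1 to 3. Ifi208, an interferon-inducible gene, had at most 1.18 CPM in any library. The difference was 2.02 ± 0.71 for Acta1 and -1.37 ± 0.56 for Postn (adjusted p = 0.992 for both). The differences were -0.58 ± 1.05 for Nppa, -1.64 ± 1.09 for Nppb, 0.14 ± 1.27 for Myh7, 0.54 ± 0.85 for Myh6, 0.30 ± 0.56 for Atp2a2 and -0.54 ± 0.73 for Col1a1, each with an adjusted p of at least 0.992. Lmnb2 itself differed by 1.90 ± 0.84 (adjusted p = 0.992), and Lmnb1 and Lmna by 1.16 ± 0.85 and -0.22 ± 0.38. edgeR called 0 genes, with 434 at an unadjusted p under 0.05 where 731 are due by chance, limma-voom 0 and DESeq2 2, Il1b (adjusted p = 0.0114) and 2610507I01Rik (adjusted p = 1.5e-05). A simulated 4-fold difference of responses was recovered for 6% of genes and a 2-fold difference for 0%.

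The size of the whole response was compared over the 3162 genes chosen without genotype. The median change was 1.31 in WT and 1.06 in KO, and 70.2% of the genes responded less in KO. The median difference was -0.24 (exact permutation of genotype labels over 200 arrangements, 2-sided p = 0.235; smallest possible 0.005), with -0.29 for genes that rose (p = 0.21) and -0.21 for genes that fell (p = 0.315). Per library the median shift from sham was 1.51, 1.45 and 0.99 in WT TAC 1 to 3, and 0.79, 1.20 and 1.21 in KO TAC 1 to 3. WT TAC 3 and KO TAC 1, the TAC libraries with the smallest shifts, were also those with the lowest ribosomal protein shares. The difference was -0.44 without WT TAC 3 (exact p = 0.05), and -0.15 without WT TAC 1.

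Of the 32 lists 9 passed in the interaction with the preset correlation, and 0 with an estimated correlation (adjusted p = 0.323 to 0.915) or with fry, and 0 of their genes were called by edgeR, DESeq2 or limma-voom. Matrix genes had a median difference of responses of -0.57, fibroblast markers of -0.54 and respiratory chain genes of -0.60, a value that was -0.000315 with the ribosomal protein share as a covariate. Cell cycle, interferon response and tricarboxylic acid cycle genes had medians of 0.42, 0.28 and 0.16, adipocyte markers of -6.23 with the gene at 0 counts set to its bound, skeletal muscle markers of -1.79, and neutrophil and mast cell markers of 2.36. The cell cycle list did not pass without KO TAC 1, the respiratory chain list without WT sham 2 or KO TAC 1, and the neutrophil and mast cell list without KO TAC 3 or with a filter of at least 1 CPM. Fibroblast, interferon response and tricarboxylic acid cycle lists passed in 9, 5 and 4 of 15 settings. None of these 3 passed with the title letter as a covariate, or without WT sham 1, KO sham 2 or KO TAC 2. Adjusted over the list alone, 5 neutrophil and mast cell markers were higher, and 4 adipocyte and 1 skeletal muscle marker lower. At an unadjusted p under 0.05 the counts of these lists ran from 0 for 3 of them to 6 of 40 cell cycle genes and 6 of 13 neutrophil and mast cell markers.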

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

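The tests of dividing cells, of swapped labels, of scaling and of a sham library labelled TAC, and the settings for transcript length and ribosomal protein share, were chosen only after the result was seen.

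In 92 tests of single libraries against the rest of the 5 sham or 6 TAC libraries, 8 lay far from the others, where chance gives about 1 in 20 groups, or 4.6. WT sham 1 had a hypertrophy and fetal gene score of 0.22 (nearest library -0.00152), and WT sham 2 a pericyte and smooth muscle score of -0.51 (nearest 0.10) and a neutrophil and mast cell score of 1.55 (nearest -0.25). KO TAC 3 had a neutrophil and mast cell score of 1.79 (nearest 0.10) and KO TAC 1 a lamina and envelope score of 0.22 (nearest 0.02). WT TAC 3 had a cytokine and chemokine score of -0.20 (nearest 0.37) and WT TAC 1 a lymphocyte score of -0.97 (nearest -0.22). Nppa was lowest among TAC libraries in KO TAC 1, at a log2 CPM of 6.62 (nearest 9.40).

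In 9 gene lists the responses to TAC differed between the genotype labels with the preset correlation, and in 0 with an estimated correlation or with fry. The median differences were -0.57 for matrix genes, -6.56 for adipocyte markers, 2.36 for neutrophil and mast cell markers, -0.60 for respiratory chain genes and 0.42 for cell cycle genes. They were -1.79 for skeletal muscle markers, -0.54 for fibroblast markers, 0.16 for tricarboxylic acid cycle genes and 0.28 for interferon response genes. The neutrophil and mast cell list did not pass without KO TAC 3 or with a filter of at least 1 CPM, the cell cycle list without KO TAC 1, and the respiratory chain list without WT sham 2 or KO TAC 1. Fibroblast, interferon response and tricarboxylic acid cycle lists passed in 9, 5 and 4 of 15 settings. The adipocyte scores were 1.36, 0.79 and 3.52 in WT TAC 1 to 3 and -1.40, -1.73 and -1.19 in KO TAC 1 to 3, and the adipocyte median was -6.23 with the gene at 0 counts set to its bound.

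The respiratory chain difference of -0.60 was weighed against library make-up. With the ribosomal protein share as a covariate it was -0.000315. A difference in make-up between libraries, technical or biological, may account for it. This setting cannot decide that, since the score and the share were nearly the same measure over the TAC libraries. Such a covariate takes away a difference in the score whatever its cause. The score followed that share over the 6 TAC libraries (r = 0.994, exact permutation p = 0.00139; rank correlation 1; 0.962 without KO TAC 1 and WT TAC 3). It followed the mitochondrial share about as closely (r = -0.971, exact permutation p = 0.00139; rank correlation -1). That share was not used as a covariate, so these 2 measures of make-up cannot be told apart. Removing each library's trend on transcript length left -0.273 and leaving out WT TAC 1 left -0.273, between the bounds set for and against these explanations. The genotype label gave an exact permutation p of 0.34, which does not show that the responses were alike, so these 3 explanations cannot be told apart.

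Lmnb2 was not lower in libraries labelled KO after TAC. Swapped labels between WT TAC and KO TAC stay open. By Gh 0 of 11 libraries went against their genotype label, but Gh was picked because it parts the labels. Of 462 splits of the libraries 417 (90.3%) parted some gene with 0 counts on one side and at least 1 in each library of the other, 27 (5.84%) at a minimum of 3 and 4 (0.866%) at a minimum of 5, and the minimum was chosen after seeing Gh. Of the 9 exchanges of a WT TAC with a KO TAC library 8 parted some gene at a minimum of 1 count, and 0 at a minimum of 2 to 7. Lmnb2 from dividing cells in the bulk tissue may add to the count (r = 0.839 with the cell cycle score over 6 TAC libraries, exact permutation p = 0.0153), but the rank correlation was 0.657 (exact p = 0.175) and r was 0.0414 without KO TAC 1 and WT TAC 2. This explanation stays open, and the condition on r without these libraries was itself set after the values were seen. Incomplete deletion, or transcripts that lack only the floxed exons, stay open and were not tested, since the table gives 1 count per gene.

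KO TAC 1 had the highest cell cycle score of the TAC libraries, 1.18 above the mean of the other KO TAC libraries. A larger share of macrophages or lymphocytes is argued against. The lymphocyte score was higher there by 2.06% of that difference, and the macrophage score differed by -0.0829. Whether immune cells that were present divided more cannot be told from these 2 scores. A scaling factor moves all genes of a library alike, and is argued against because the cell cycle score moved at least 1.16 further than these 2 scores, while KO TAC 2 and 3 differed by at most 0.0827 in the same distance. This replaced an earlier test with library totals alone (108% of the difference left) and a later one against the median of all other genes (98.3%), whose outcomes TMM largely fixed. A sham library labelled TAC is argued against by a matrix score 2.35 above the highest sham library, beyond the sham range of 0.66. Other sources of dividing cells stay open, and no other biological explanation was tested, as the design gives none for a single library.

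Of the 10 splits of the 6 KO libraries, 1, the real one, gave 687 genes and the highest other 0. Of the 10 splits of the 6 TAC libraries all 10 gave at least the real 0 genes, and the highest other gave 831. Both sets are too few for a share under 0.05. The split with 831 set WT TAC 1, WT TAC 2 and KO TAC 3 against the rest, which points to a structure of the samples, and these held the 3 highest ribosomal protein shares of the TAC libraries. Over both genotypes 100 splits were run, the real one and others drawn at random. Of these 2, the real one among them, reached the real 3162 genes, a share under 0.05. The other gave 3295. That split set KO sham 1, WT TAC 1, WT TAC 2, KO TAC 2 and KO TAC 3, the 5 libraries with the highest ribosomal protein shares, against the rest. It overlaps with surgery, since of these only KO sham 1 is a sham library, and only WT TAC 3 and KO TAC 1 lie with the sham libraries. It is thus not a structure apart from surgery. As it parted as many genes, the count alone does not tell surgery from the ribosomal protein share.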

How the results depend on the processing

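The tests with transcript length or GC trends removed, with the ribosomal protein share as a covariate, without KO TAC 1 and WT TAC 3 together, and of named genes with limma-voom were chosen only after the result was seen. Unless stated, the cause of a change was not tested.

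The 1011 genes called after TAC in WT became 2018 at an adjusted p under 0.1, 2197 with DESeq2, 2243 with no low count filter, 608 with the title letter as covariate, 204 in titles ending in M (fewer samples), 465 with only the groups compared (fewer samples), 1615 with the transcript length trend removed and 4374 without KO TAC 1 and WT TAC 3 together. Leaving out 1 library gave 30 (without WT sham 1) to 2663 (without WT TAC 3). The 687 in KO became 1261 at an adjusted p under 0.1, 1499 with DESeq2, 1385 with library totals alone, about 1.3e+03 with no low count filter, 102 in titles ending in M, 1083 with the length trend removed, 2324 with the ribosomal protein share and 2117 without both libraries, and 226 (without KO sham 1) to 996 (without WT TAC 3) with 1 library left out.

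The 0 genes between KO and WT after sham became 3 with DESeq2, 20 with no low count filter, 4 with only the groups compared and 2 without KO TAC 1 and WT TAC 3. After TAC 0 became 6 with DESeq2, 206 with no filter and 14 without both libraries, and in the interaction 2, 80 and 1. Leaving out any 1 library gave 0 with edgeR in these 3 comparisons, and limma-voom gave 0. Over both genotypes 3162 became 2017 with a log2 fold change of at least 1, 1836 in titles ending in M and 5760 without both libraries, and 2216 (without WT sham 1) to 4441 (without KO TAC 1).

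Of the lists, 13, 12, 9, 8 and 9 passed in TAC against sham in WT and KO, KO against WT after sham and TAC, and the interaction. With an estimated correlation 2, 3, 0, 0 and 0 passed, with fry 12, 12, 0, 0 and 0, and in the interaction 4 with a filter of at least 1 CPM. Leaving out 1 library gave 10 to 15, 12 to 15, 4 (without WT sham 2) to 11, 5 (without WT TAC 3) to 10, and 5 (without KO TAC 1) to 9.

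The response size of -0.24 kept its sign in all settings run, from -0.34 to -0.12, and from -0.44 to -0.15 (exact p = 0.05 to 0.61) with 1 library left out. Lmnb2 between KO and WT ran from -1.71 to -0.97 after sham, and after TAC from -0.0663 (without KO TAC 1) to 1.24 (without WT TAC 3). Its change after TAC in WT, -0.08, turned to 0.28 with library totals, 0.00522 with the title letter, 0.71 with the ribosomal protein share. It was also positive without WT sham 1, WT TAC 1 or WT TAC 2, and ran from -0.73 (without WT TAC 3) to 0.22 (without WT TAC 2). Between KO and WT after sham Lmnb1 was -0.0534 with limma-voom, was negative without WT sham 1 or KO sham 1 and ran from -0.38 (without KO sham 1) to 0.32 (without KO sham 3). Lmna turned to 0.11 without WT sham 1.

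In the interaction Myh6 turned to -0.0911 with the ribosomal protein share and ran from -0.35 (without KO TAC 1) to 1.35 (without WT TAC 3); Atp2a2 turned to -0.11 and ran from -0.19 to 0.60 without the same libraries. Myh7 was negative without WT sham 1, KO sham 1, WT TAC 1, WT TAC 2 or KO TAC 3, and ran from -0.40 (without WT TAC 2) to 2.73 (without WT TAC 3). Col1a1 ran from -0.92 (without KO sham 1) to 0.0696 (without KO sham 2). None of these genes had passed. Of 130 calls of named genes 0 turned direction; 130 passed with DESeq2 and with RLE size factors, 128 with no filter, 118 with the ribosomal protein share, 107 with the title letter, 105 with library totals, 103 with limma-voom, and 64 (without WT sham 1) to 130 (without WT TAC 3) with 1 library left out. Tagln in WT was lost in 12 settings, and Atp2a2, Pln and Il1b in WT and Chrna2 and Sbk2 in KO in 11 each.

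No paired analysis was possible because nothing in the labels pairs the samples. Without a WT sham library, the lone one left is assumed to vary like the other groups. Depth limits single libraries to 0.143 to 0.278 CPM at 3 counts, which bears on Gh, Il1b, Mylpf and Ifi208.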

Other observations

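The test of genotype over both surgeries was chosen only after the result was seen.

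With KO set against WT over both surgeries edgeR called 0 genes (479 at an unadjusted p under 0.05, 731 due by chance), limma-voom 0 and DESeq2 1, Gh (adjusted p = 1.9e-05). The source of the Gh counts was not tested.

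Over both genotypes, TAC against sham called members of lists with no or few calls in either genotype alone. This fit called 3162 of 14619 genes, and the counts below are to be read against that share. Of 43 respiratory chain genes 13 fell (median -0.28, with a list adjusted p of 0.000166 with the preset correlation and 0.581 with an estimated one). The other lists of this paragraph did not pass, with list adjusted p of 0.157 or more with the preset correlation. Of 19 circadian genes 5 fell, Per3, Nr1d2, Dbp, Tef and Hlf. Among 25 lamina and envelope genes Lmna and Lmnb1 rose, and Tor1aip1 and Plpp7 fell. Of 30 nuclear pore genes 1 fell, Ndc1, and of 31 transport receptor genes 2 fell, Kpna6 and Ipo13. In the integrated stress list 7 rose and 2 fell, Hspa5 and Herpud1, in the ERK list 4 rose, among atrial markers 4 rose and 3 fell, and among immediate early genes 4 rose and 1 fell. Of Schwann cell and neuron markers 1 rose and 2 fell, of red blood cell genes 1 rose, and of lymphocyte, endothelial, adipocyte and neutrophil and mast cell markers 0 were called by edgeR. Genes in this paragraph were named after their values were seen.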
